A study of Homo sapiens with 12 samples.

How the data were processed

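Polyadenylated RNA was sequenced in 12 libraries of shA673-1c, a derivative of the Ewing sarcoma cell line A673 that carries a doxycycline-inducible short hairpin RNA against the fusion transcript EWS::FLI1. Per the labels' protocols, the cells received doxycycline at 1 µg per ml for 4 days and then 5 µM actinomycin D, an inhibitor of transcription, and RNA was taken after 0, 1, 2 and 4 h. Each time point had 3 biological replicates. RNA was purified with a Nucleospin kit and libraries were made with a stranded Illumina TruSeq mRNA kit, per the labels' protocols.

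The deposited table held raw read counts per gene symbol, made by the authors. FastQC, STAR and the human genome build hg19 are named without versions, per the submitters' processing notes. The program that counted the reads, the gene annotation and the strand setting were not given in the sources used here. Reads of near-identical genes, and of genes that overlap on opposite strands, could therefore have been split or shared, which bears on the ANKRD36 and GOLGA8 families, on ribosomal protein genes with processed pseudogenes, and on antisense transcripts. The deposited counts carry gene symbols and no coordinates, so no positions are given.

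The table listed 26334 genes, of which 7175 had no count in any library. Total counts lay between 9381855 and 10929000 per library. Intervals and limits from such totals would cover counting error only. No pair of replicates was identical, and the chi-square of their counts per degree of freedom was 4.13 to 15.2, so each library was counted as 1 replicate.

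Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the time groups, which left 12775, and libraries were scaled by TMM. Dispersions were estimated over all 12 libraries, and the quasi-likelihood test was applied to 1 h, 2 h and 4 h against 0 h, to a slope of log2 expression per hour over the 4 time points, and to a change of rate, the log2 change from 2 to 4 h minus that from 0 to 2 h. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, with a threshold of 0.05. Standard errors are the absolute log2 change divided by the square root of the quasi-likelihood F. CPM, computed by edgeR from TMM-scaled totals unless raw totals are named, are given as mean ± SD over 3 replicates. No spike-in was part of the table. Because actinomycin D shrinks the mRNA pool, every change is relative to the other mRNAs of the library, and an mRNA that is lost more slowly than the average appears higher.

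Gene lists, the design, the alternatives and the rule for naming genes were chosen before the data were examined. The 27 lists covered immediate early and inducible genes, developmental and inducible transcription regulators, C2H2 zinc finger genes named ZNF, cytosolic ribosomal proteins, translation factors, oxidative phosphorylation, glycolysis, proteasome, histones, mRNA decay, genes described as activated or repressed by EWSR1::FLI1, extracellular matrix, G2/M and G1/S genes, p53-linked and NF-kappa-B linked genes, apoptosis regulators, cholesterol synthesis, stress responses, heat shock proteins, snoRNA host genes, nuclear long noncoding RNAs, splicing factors, cytoskeleton, mitochondrially encoded mRNAs and markers of other cell types. The 25 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists. The lists were also tested with fry in limma, which tests the members of a list without comparing them with the other genes. List names are labels for the members chosen, and where a long noncoding RNA lies in the cell was not measured. No mitochondrially encoded mRNA was in the table. Of the markers of blood, epithelium and liver, 13 were in the table, none passed the filter, and the highest mean was 0.469 CPM of raw totals.

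Named genes were, per comparison with 0 h, the 8 largest falls and the 8 largest rises among genes past the threshold with at least 5 CPM on average and no overlap between the libraries of both times, a separation that chance gives in 10% of draws of 3 against 3. For the change of rate, the 4 largest in each direction were taken. For each list, up to 4 members with the smallest adjusted p at 4 h were taken, and FLI1, EWSR1, GAPDH, ACTB and MYC were always included. Some genes that met this rule are not reported here.

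The replicate numbers in the labels were shared by the 4 time points, and they paired the libraries. Deviations from the group means correlated at 0.369 to 0.494 among libraries of replicate 1, at 0.263 to 0.336 in replicate 2 and at 0.575 to 0.649 in replicate 3, against -0.501 to 0.16 between different numbers, and 12 of 12 libraries were closest to a library of their own number. The replicate block, a model with the replicate number as a covariate, is therefore given where it changed a call or moved a count by over 1.5 times. The labels call the replicates biological, and the block does not say what the libraries of one number shared.

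Alternatives were upper-quartile scaling, DESeq2 size factors, library totals alone, scaling to the summed counts of the ribosomal protein list, no filter, a filter at 5 CPM, the Wald test of DESeq2 1.42.0, limma-voom, a test against a 1.5-fold change, fits on the compared time points alone, and leaving out each library. The fits that left out libraries used the model without the replicate block. Whether calls lost there rest on differences between replicate numbers was not tested. Against TMM, scaling by library totals moved the median log2 change of all genes at 4 h by -0.15, and scaling to ribosomal protein mRNAs moved it by -0.37 at 4 h and by -0.14 at 2 h. Transcript properties were taken from GENCODE annotation matched by symbol, current or older.

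In simulated counts, 200 genes changed steadily over 4 h and 200 others changed only after 2 h. The pipeline was tested on these counts, drawn at the means and depths of these libraries, in 12641 tested genes. At 4 h it recovered 58.2% of 1.5-fold, 80.6% of 2-fold and 93.9% of 4-fold changes, with 11 false calls among 321. The slope recovered 62.7%, 83.6% and 95.5% of these sizes. The change of rate recovered 11.9% of 1.5-fold, 31.3% of 2-fold and 80.3% of 4-fold differences, so the model without the replicate block mostly missed smaller differences of rate. A list of lowered genes had an adjusted p of 9.11e-39 with camera, and 0 of 50 random lists were called. Genes were drawn independently, so these lists held no correlation between genes such as the 0.398 estimated for the ribosomal proteins. False list calls at such correlations were not measured. Rises and falls were equal in number and the pool did not shrink, so the scaling was not tested. The libraries were drawn without shared replicate numbers and the replicate block was not run on them, so its recovery was not measured.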

Results

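The data were 12 RNA-seq libraries of shA673-1c Ewing sarcoma cells, all treated with doxycycline for 4 days to knock down EWS::FLI1, per the labels, and sampled in triplicate at 0, 1, 2 and 4 h of 5 µM actinomycin D. Blocking transcription lets the abundance of each mRNA follow its loss, so the time course asks which transcripts are short-lived and which are long-lived in the treated cells. Mean totals per time point were 10480743 counts at 0 h, 10210121 at 1 h, 10192812 at 2 h and 9939173 at 4 h. The first principal component held 59.0% of the variance and followed time, and the second held 15.9% and set replicate 3 apart at every time point. The 10 most abundant genes took 7.51% ± 0.272 of the counts at 0 h and 8.99% ± 0.168 at 4 h (SD, n = 3). FN1, which encodes fibronectin, took 2.60% ± 0.259 at 0 h and 3.40% ± 0.266 at 4 h.

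FLI1 reads, which in these cells include the part of FLI1 held in the fusion transcript, were present in every library. FLI1 stood at 20.5 ± 1.05 CPM at 0 h, 14.8 ± 4.30 CPM at 1 h, 11.1 ± 2.18 CPM at 2 h and 7.42 ± 0.639 CPM at 4 h. Its log2 change at 4 h was -1.46 (SE 0.20, edgeR adjusted p = 7.016e-05), a 2.76-fold fall, lower in 3 of 3 replicates. At 1 h its log2 change was -0.48 (adjusted p = 0.3729), which passed the threshold only with the replicate block (adjusted p = 0.006627). EWSR1, the other fusion partner, went from 236 ± 28.9 to 296 ± 29.7 CPM, a log2 change of 0.33 (SE 0.11, adjusted p = 0.02604) that turned to -0.05 when libraries were scaled to ribosomal protein mRNAs. The EWSR1 call ended without 0 h replicate 3, 4 h replicate 1 or 4 h replicate 2 (adjusted p from 0.0843 to 0.129). These fits used the model without the replicate block, and with the block and all libraries the call held. EWSR1 went from 244, 260 and 204 to 312, 314 and 262 CPM in replicates 1, 2 and 3. Libraries without doxycycline were not analysed here, so the size of the knockdown was not measured. The hairpin against the fusion transcript was induced in every library. Loss through the hairpin and other loss of FLI1 mRNA therefore cannot be told apart in its fall or in its slope.

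Among genes with at least 5 CPM and no overlap between both times, the rule for naming genes, the largest fall after 1 h was that of GADD45B, a stress-inducible regulator of kinase signalling, which went from 24.0 ± 3.72 to 6.11 ± 1.93 CPM, a 3.94-fold fall (log2 change -1.98, SE 0.29, edgeR adjusted p = 0.005418). DDIT4, an inhibitor of mTORC1 signalling, fell 3.57-fold from 37.7 ± 8.16 to 10.5 ± 2.78 CPM, and DUSP6, a phosphatase that acts on ERK, fell 2.89-fold from 249 ± 9.19 to 85.9 ± 2.96 CPM. The pseudokinase gene TRIB1, the zinc finger genes ZNF267 and ZNF254, the stress factor gene DDIT3 and LOC284454 completed the 8 largest falls, with log2 changes of -1.73, -1.60, -1.50, -1.43 and -1.70. Rises were smaller. HSF4, a heat shock transcription factor, had a log2 change of 0.98 (SE 0.15, adjusted p = 0.008816), and GOLGA8A, whose reads can be shared with its near-identical copy GOLGA8B, one of 0.90 (SE 0.09, adjusted p = 0.001031). AMH, the anti-Müllerian hormone gene, had the largest rise under that rule with 1.17 (SE 0.23, adjusted p = 0.02332), and its call ended without 0 h replicate 1, 0 h replicate 3, 1 h replicate 2 or 1 h replicate 3 (adjusted p from 0.0804 to 0.111).

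In total, 148 genes were lower and 22 higher at 1 h, against 802 and 322 with the replicate block, and all 148 and 22 were among the blocked calls. A fall of over 2-fold was called for 53 genes and a rise of that size for 3. The lower count was 58 and 45 without 0 h replicates 1 and 2, and 76, 44 and 47 without 1 h replicates 1, 2 and 3. The higher count was 12, 7 and 8 without 0 h replicates 1, 2 and 3, and 9 and 5 without 1 h replicates 2 and 3. Of the immediate early and inducible genes, 11 of 35 fell (22 adjusted over the list alone, 26 with the replicate block), with a list median of -0.54 and a camera adjusted p of 5.8e-18. Among C2H2 zinc finger genes named ZNF, 43 of 365 fell and 1 rose (110 and 2 adjusted over the list alone, 127 and 3 with the block), with a median of -0.31 and a camera adjusted p of 1.21e-25. Of the developmental and inducible transcription regulators, 5 of 41 fell (8 adjusted over the list alone, 17 with the block) at a camera adjusted p of 1.37e-08. With an estimated correlation these list calls held, at adjusted p = 0.0285, 0.000482 and 0.0144. With that correlation and the replicate block together the ZNF call held (adjusted p = 0.0121), while the immediate early genes (adjusted p = 0.124) and the transcription regulators (adjusted p = 0.0787) missed the threshold. The snoRNA host genes had 1 of 20 lower (1 adjusted over the list alone, 6 with the block), with a median of -0.19 and a camera adjusted p of 4.52e-05 that became adjusted p = 0.0877 with an estimated correlation and passed with that correlation and the block together (adjusted p = 0.0334). The extracellular matrix list had a camera adjusted p of 0.00771 at a median of 0.04, with 0 of 44 members called (0 adjusted over the list alone, 6 higher with the block). That list call was lost with an estimated correlation (adjusted p = 0.295) and without 0 h replicate 1 (adjusted p = 0.146).

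Under the same naming rule, the largest fall after 2 h was that of NFKBIA, which encodes the NF-kappa-B inhibitor I-kappa-B alpha and went from 39.8 ± 3.13 to 2.54 ± 0.692 CPM, a 15.6-fold fall (log2 change -3.97, SE 0.20, edgeR adjusted p = 1.123e-07). DDIT4 was 14.7-fold lower, DUSP6 11.8-fold lower, HES1, a transcriptional repressor downstream of Notch, 11.6-fold lower, TRIB1 11.1-fold lower and SOCS3, an inhibitor of JAK-STAT signalling, 10.1-fold lower. GADD45B was 8.99-fold lower and JUN, a subunit of the AP-1 transcription factor, fell 8.28-fold from 115 ± 10.8 to 13.9 ± 2.41 CPM. MYC fell from 86.9 ± 12.6 to 12.7 ± 2.28 CPM (log2 change -2.78, SE 0.19, adjusted p = 1.199e-06). The largest rise under the rule was that of ANKRD36, 2.11-fold from 5.24 ± 2.11 CPM (log2 change 1.07, SE 0.22, adjusted p = 0.005116), whose reads can be shared with other ANKRD36 family members. HSF4 (0.88) and GOLGA8A (0.86) remained higher, and the long noncoding RNA LINC00342 had a log2 change of 0.89 (adjusted p = 0.01285), a call that ended without 0 h replicate 2 (adjusted p = 0.0644).

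At 2 h, 1496 genes were lower and 433 higher, against 2496 and 2037 with the replicate block. Scaled by library totals the split was 1762 lower and 143 higher, and scaled to ribosomal protein mRNAs it was 2188 lower and 25 higher. The higher count was 214, 147 and 259 without 0 h replicates 1, 2 and 3, and 135 and 208 without 2 h replicates 2 and 3. Of the immediate early and inducible genes 29 of 35 fell (30 adjusted over the list alone), with a median of -1.59 and a camera adjusted p of 7.29e-23. Of the ZNF genes 228 of 365 fell and 3 rose (265 and 3 adjusted over the list alone), with a median of -0.80 and a camera adjusted p of 4.01e-44. The transcription regulators followed with 24 of 41 lower (30 adjusted over the list alone) and a median of -0.77 (camera adjusted p = 1.45e-14). With an estimated correlation these calls held, at adjusted p = 0.0138, 6.13e-05 and 0.00233, and with the block added the immediate early call was lost (adjusted p = 0.0939). Among cytosolic ribosomal proteins 13 of 79 rose and 1 fell (24 and 1 adjusted over the list alone, 54 and 1 with the block, 2 and 1 under library totals, 0 and 1 under ribosomal scaling), with a median of 0.15 that was 0.01 under ribosomal scaling. Among oxidative phosphorylation genes 13 of 80 rose and 1 fell (28 and 1 adjusted over the list alone, 44 and 1 with the block, 4 and 1 under library totals, 0 and 1 under ribosomal scaling), with a median of 0.16, or 0.02 under ribosomal scaling. Their camera adjusted p-values of 3.93e-10 and 4.41e-10 became adjusted p = 0.336 and adjusted p = 0.184 with an estimated correlation.

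Other lists called by camera at 2 h were small in effect. Of the translation factors 4 of 34 rose (3 adjusted over the list alone, 21 higher and 1 lower with the replicate block, 0 higher and 1 lower under library totals and under ribosomal scaling), with a median of 0.13 that turned to -0.01 under ribosomal scaling. Of the glycolysis genes 2 of 20 rose (2 adjusted over the list alone, 11 with the block, 1 under library totals, 0 under ribosomal scaling), with a median of 0.11 that turned to -0.03 under that scaling. Of the proteasome genes 6 of 36 rose (7 adjusted over the list alone, 17 with the block, 1 under library totals, 0 under ribosomal scaling), with a median of 0.12 that turned to -0.02 under the same scaling. Of the matrix genes 9 of 44 rose (11 adjusted over the list alone, 28 with the block, 5 under library totals, 0 under ribosomal scaling), with a median of 0.12 that turned to -0.02 under ribosomal scaling. Of the p53-linked genes 5 of 23 fell (6 adjusted over the list alone, 11 lower and 2 higher with the block, 6 lower under library totals, 8 under ribosomal scaling), with a median of -0.22. Of the snoRNA host genes 5 of 20 fell (9 adjusted over the list alone, 12 lower and 1 higher with the block, 8 lower under library totals, 9 under ribosomal scaling), with a median of -0.28. Of the nuclear long noncoding RNAs 2 of 11 rose (3 adjusted over the list alone, 5 higher and 1 lower with the block, 1 higher under library totals, 1 higher and 1 lower under ribosomal scaling), with a median of 0.30 that was positive under every scaling tried. In this order the camera adjusted p-values were 0.000272, 0.00193, 3.58e-05, 3.58e-05, 0.0302, 0.00785 and 0.0406. All 7 calls were lost with an estimated correlation, at adjusted p = 0.407, 0.249, 0.249, 0.123, 0.128, 0.249 and 0.249. The last of them also ended without 0 h replicate 2, 0 h replicate 3 or 2 h replicate 3 (adjusted p from 0.0605 to 0.0967). The NF-kappa-B linked genes and the cytoskeleton were called only with the block (adjusted p = 0.0199 and 0.0418, against 0.0585 and 0.16), and with the block and an estimated correlation both missed the threshold (adjusted p = 0.218 and 0.582).

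After 4 h the 8 largest falls under the naming rule exceeded 20-fold. NFKBIA was 43.7-fold lower, at 0.900 ± 0.428 CPM (log2 change -5.45, SE 0.24, edgeR adjusted p = 3.644e-09), and DDIT4 35.7-fold lower. PLK2, a polo-like kinase gene, fell 33.8-fold from 158 ± 31.1 to 4.66 ± 0.318 CPM. DUSP1, a phosphatase that acts on MAP kinases, fell 29.4-fold, HES1 27.3-fold, SNAI1, a repressor of epithelial genes, 25.7-fold, and SERTAD3 25.2-fold. CITED2, which binds the coactivators CBP and p300, fell 20.8-fold. MYC fell 20.1-fold to 4.34 ± 0.967 CPM (log2 change -4.33, SE 0.22, adjusted p = 1.067e-08). Each of these genes was lower at 4 h than at 0 h in 3 of 3 replicates, which the naming rule required of all but MYC.

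The largest rise at 4 h under the naming rule was that of MALAT1, an abundant long noncoding RNA retained in the nucleus, which went from 161 ± 13.6 to 614 ± 111 CPM, a 3.82-fold rise (log2 change 1.93, SE 0.16, edgeR adjusted p = 9.194e-07). ANKRD36 rose 3.65-fold and ANKRD36C 3.38-fold, AMH rose 3.35-fold, KCNQ1OT1, an imprinted RNA transcribed antisense to KCNQ1, rose 2.79-fold, CCDC84 rose 2.75-fold and BRICD5 rose 2.68-fold. These 7 genes stayed higher under ribosomal scaling, with MALAT1 at a log2 change of 1.56 (adjusted p = 1.69e-06). IGFN1 had a log2 change of 1.68 (SE 0.50, adjusted p = 0.01421) over widely spread libraries, 20.5 ± 13.2 CPM at 0 h and 65.6 ± 30.9 CPM at 4 h. Its call ended under ribosomal scaling (log2 change 1.304, adjusted p = 0.0508) and without 0 h replicate 2 (adjusted p = 0.06), 0 h replicate 3 (adjusted p = 0.0525) or 4 h replicate 1 (adjusted p = 0.0741). IGFN1 was higher at 4 h in 3 of 3 replicates, which the naming rule required, and passed with the replicate block (adjusted p = 1.07e-13). GAPDH, a glycolytic enzyme gene often used as a reference, rose 1.36-fold (log2 change 0.44, SE 0.09, adjusted p = 0.001737), which was 0.07 (adjusted p = 0.668) under ribosomal scaling. ACTB, which encodes beta-actin, rose 1.26-fold (log2 change 0.33, SE 0.09, adjusted p = 0.01131), which turned to -0.04 under ribosomal scaling. The ACTB call also ended under library totals (0.18, adjusted p = 0.106) and without 0 h replicate 3 (0.25, adjusted p = 0.0661). The latter fit used the model without the replicate block, and with the block and all libraries the call held under TMM. ACTB went from 4660, 4564 and 4046 to 5945, 5678 and 5086 CPM in replicates 1, 2 and 3.

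**Figure D1:**
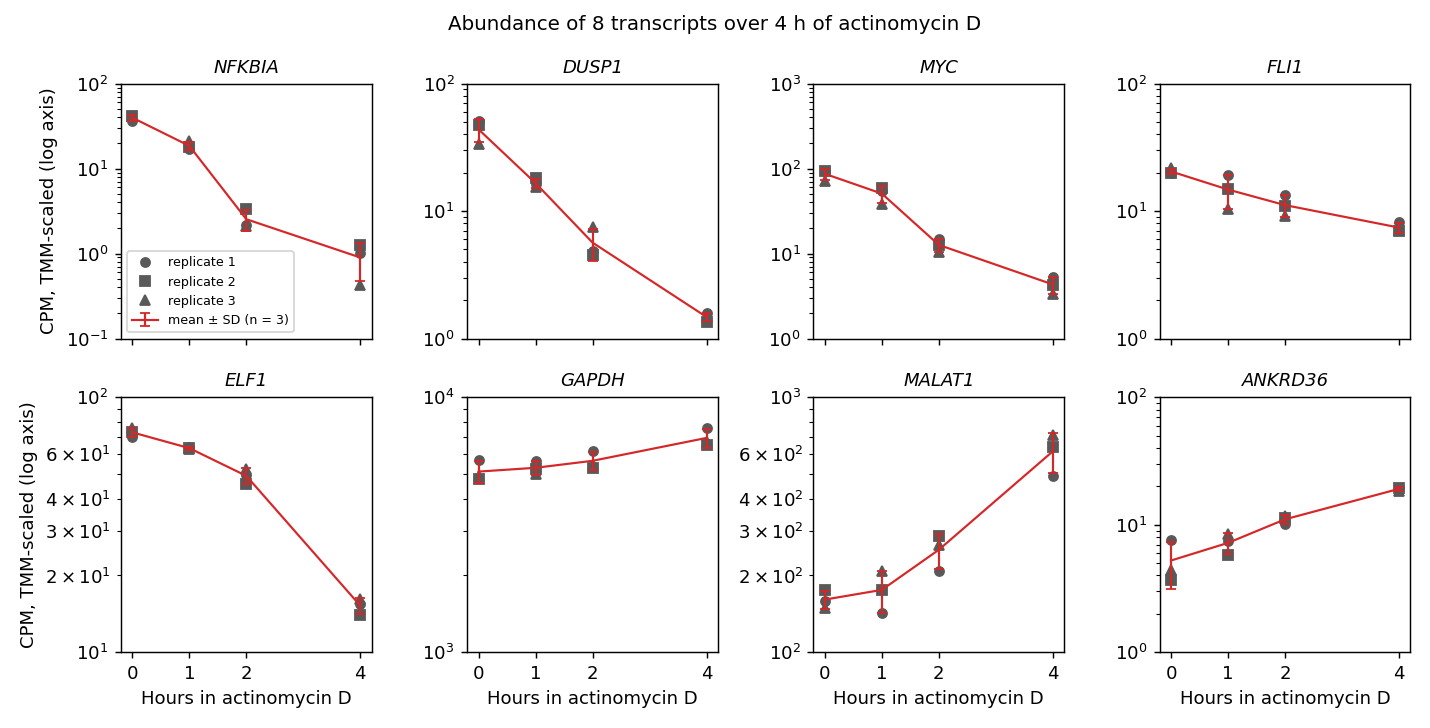
CPM scaled by TMM (log axes, which differ between panels) against hours in actinomycin D for 8 genes; grey symbols are single libraries of replicates 1 to 3 and red lines the mean ± SD (n = 3). NFKBIA fell to 0.900 CPM and MYC to 4.34 CPM at 4 h, ELF1 kept 63.2 CPM at 1 h and had 15.2 CPM at 4 h, MALAT1 rose to 614 CPM, and the rise of GAPDH was near 0 (log2 change 0.07) when scaled to ribosomal protein mRNAs.

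Counts at 4 h were 3148 lower and 2975 higher genes of 12775 tested. The changes were unequal in size, with a fall of over 2-fold called for 1455 genes and a rise of over 2-fold for 105. The 5th and 95th percentiles of the log2 change over all tested genes were -1.79 and 0.59, around a median of 0.05. Scaled by library totals the split was 3961 lower and 1346 higher, and scaled to ribosomal protein mRNAs it was 5854 lower and 154 higher. All 3148 lower genes were also called lower under both of these scalings, which follows from the scalings, since both move all genes down together at 4 h.

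Short-lived regulators were lower as groups at 4 h. Of the immediate early and inducible genes 31 of 35 fell and 0 rose (33 and 0 adjusted over the list alone), with a median log2 change of -2.69 and a camera adjusted p of 1.06e-15. DUSP6 fell 19.2-fold, JUN 20.7-fold, IER2 13.7-fold and PHLDA1, from 369 ± 13.6 CPM, 6.45-fold. Of the developmental and inducible transcription regulators 32 of 41 fell and 0 rose (34 and 0 adjusted over the list alone), with a median of -1.77 and a camera adjusted p of 7.38e-13, among them SOX11, a neural SOX factor, at 4.16-fold. Of the ZNF genes 281 of 365 fell and 7 rose (291 and 9 adjusted over the list alone, 304 and 12 with the replicate block, 300 and 2 under library totals, 328 and 0 under ribosomal scaling), with a median of -1.18 and a camera adjusted p of 4.88e-28. ZNF281 fell 15.6-fold, ZNF627 12.9-fold, ZNF217 5.90-fold and ZNF148 5.68-fold. The medians of these lists were also below 0 under every scaling tried. With an estimated correlation the calls held, at adjusted p = 0.0415, 0.00385 and 0.000345. With the replicate block added the immediate early list missed the threshold (adjusted p = 0.139).

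**Figure D2:**
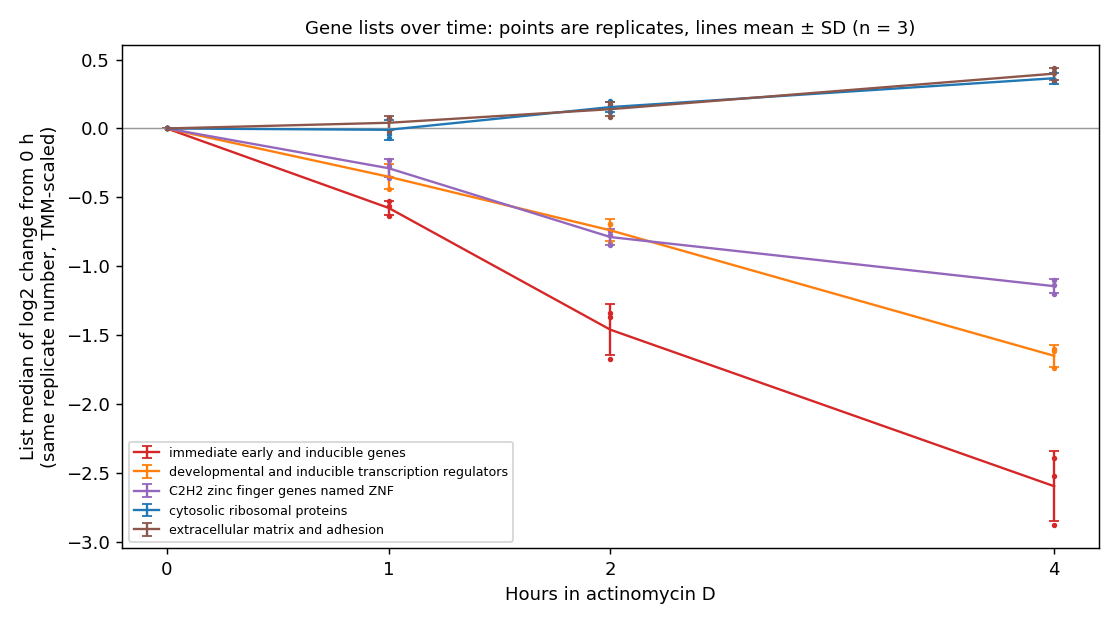
Median log2 change from 0 h of the same replicate number (TMM-scaled) for 5 gene lists, against hours in actinomycin D; points are replicates and lines the mean ± SD (n = 3). At 4 h the immediate early list stood at -2.60 ± 0.255, the transcription regulators at -1.65 ± 0.0790 and the ZNF genes at -1.15 ± 0.0510, while ribosomal proteins and extracellular matrix genes stood at 0.37 ± 0.0390 and 0.40 ± 0.0440, positions that become -0.00 and 0.03 as list medians of the fitted changes when libraries are scaled to ribosomal protein mRNAs.

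Genes of basic metabolism, protein synthesis and the matrix were higher relative to the other mRNAs at 4 h, each by a factor under 1.5 at the list median. Of the cytosolic ribosomal proteins 74 of 79 rose and 1 fell (75 and 1 adjusted over the list alone, 56 and 1 under library totals, 2 and 1 under ribosomal scaling), with a median of 0.37 that was 0.22 under library totals and -0.00 under ribosomal scaling, where it is fixed by construction. RPS19 rose 1.42-fold, RPL37A 1.38-fold and RPL23A 1.36-fold. Of the nuclear-encoded oxidative phosphorylation genes 68 of 80 rose and 1 fell (70 and 1 adjusted over the list alone, 72 and 2 with the replicate block, 40 and 2 under library totals, 2 and 7 under ribosomal scaling), with a median of 0.36, or -0.01 under ribosomal scaling. Its members ATP5J2, ATP5B and UQCRH rose 1.51-, 1.31- and 1.36-fold, and NDUFV3, a subunit of complex I, fell 1.93-fold. Of the glycolysis genes 15 of 20 rose (17 adjusted over the list alone, 12 under library totals, 0 higher and 2 lower under ribosomal scaling), with a median of 0.39, or 0.02 under ribosomal scaling, among them ENO2, GPI, LDHB and TPI1 at 1.48-, 1.36-, 1.31- and 1.31-fold. Of the extracellular matrix and adhesion genes 29 of 44 rose (32 adjusted over the list alone, 20 under library totals, 1 higher and 1 lower under ribosomal scaling), with a median of 0.40, or 0.03 under ribosomal scaling, among them the laminin genes LAMB1 (1.43-fold) and LAMC1 (1.34-fold), the protease inhibitor gene TIMP2 (1.45-fold) and the integrin gene ITGB1 (1.36-fold). Of the proteasome genes 26 of 36 rose and 2 fell (27 and 2 adjusted over the list alone, 9 and 5 under library totals, 0 and 15 under ribosomal scaling), with a median of 0.27 that turned to -0.11 under ribosomal scaling. PSMA7 rose 1.29-fold, a log2 change of 0.37 that turned to -0.003 under that scaling, and the 2 that fell were PSMD5 and PSMD12, at 1.36- and 1.32-fold. Of the translation factors 18 of 34 rose and 4 fell (18 and 4 adjusted over the list alone, 10 and 6 under library totals, 1 and 14 under ribosomal scaling), with a median of 0.20 that turned to -0.17 under ribosomal scaling, with EEF1D at 1.48-fold. Of the cytoskeleton genes 16 of 24 rose and 1 fell (16 and 1 adjusted over the list alone, 18 and 2 with the replicate block, 9 and 3 under library totals, 1 and 5 under ribosomal scaling), with a median of 0.34 that turned to -0.03 under ribosomal scaling, with PFN1 at 1.41-fold.

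The camera adjusted p was 1.53e-16 for ribosomal proteins, 1.92e-13 for oxidative phosphorylation, 2.68e-05 for glycolysis, 1.38e-07 for the matrix, 0.000143 for the proteasome, 0.00227 for translation factors and 0.00195 for the cytoskeleton. With an estimated correlation only the matrix list held (adjusted p = 0.0415), and it missed the threshold when the replicate block was added (adjusted p = 0.139). The ribosomal proteins then had adjusted p = 0.217, oxidative phosphorylation adjusted p = 0.0863, glycolysis adjusted p = 0.132, the proteasome adjusted p = 0.286, translation factors adjusted p = 0.507 and the cytoskeleton adjusted p = 0.365. Under ribosomal scaling the camera calls on the proteasome (adjusted p = 0.483) and on translation factors (adjusted p = 0.57) also ended.

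Genes that act in mRNA decay were themselves partly short-lived. Of the mRNA decay and CCR4-NOT factors 23 of 56 fell and 8 rose (24 and 13 adjusted over the list alone, 28 and 14 with the replicate block, 31 and 2 under library totals, 41 and 0 under ribosomal scaling), with a median of -0.14 and a camera adjusted p of 0.0256 that became adjusted p = 0.0863 with an estimated correlation. BTG1 and TOB2, which recruit the CCR4-NOT deadenylase, fell 14.7- and 4.72-fold, and PUM2, an RNA-binding Pumilio family gene, fell 2.22-fold. Of the p53-linked genes 11 of 23 fell and 1 rose (12 and 2 adjusted over the list alone, 12 and 3 with the block, 12 and 0 under library totals, 17 and 0 under ribosomal scaling), with a median of -0.35 and a camera adjusted p of 0.0256 that also became adjusted p = 0.0863. SESN2 fell 4.83-fold, AEN 3.48-fold and MDM2, the ubiquitin ligase of p53, 1.62-fold. Among the 11 members of the list named nuclear long noncoding RNAs 5 rose and 1 fell (6 and 1 adjusted over the list alone). The median was 0.70, positive under every scaling tried, with a camera adjusted p of 0.0507. NEAT1, the scaffold of paraspeckles, rose 2.23-fold, MEG3 rose 2.23-fold, and LINC00657, also known as NORAD, fell 1.65-fold. Where LINC00657 lies in the cell was not measured, so its fall is not read as that of a nuclear RNA.

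Targets described for the fusion had members in both directions at 4 h under TMM, whereas under ribosomal scaling none was called higher. That scaling left only 154 of all 12775 tested genes called higher, so lists this short would have few or none in any case. Of the genes described as activated by EWSR1::FLI1 7 of 20 fell and 1 rose (7 and 1 adjusted over the list alone, 8 and 6 with the replicate block, 10 and 0 under ribosomal scaling). The transcription factor genes SOX2, EGR2 and ID2 fell 17.6-, 12.1- and 5.32-fold and FCGRT, the neonatal Fc receptor gene, rose 1.46-fold, a change that was 0.18 on the log2 scale (adjusted p = 0.154) under ribosomal scaling. This list had a median of 0.03, or -0.12 under library totals and -0.34 under ribosomal scaling, a mean of -0.68 and a camera direction of lower (adjusted p = 0.497). Of the genes described as repressed by the fusion 3 of 14 fell and 2 rose (3 and 2 adjusted over the list alone, 3 and 7 with the block, 6 and 0 under ribosomal scaling). FOXO1, DKK1 and PHLDA1 fell 6.88-, 6.38- and 6.45-fold. The fold of DKK1 rests on few reads, at 0.881 to 1.133 CPM at 0 h and 0.105 to 0.212 CPM at 4 h. LOX, which encodes lysyl oxidase, rose 1.33-fold from 3823 ± 193 to 5103 ± 238 CPM, a log2 change of 0.42 that was 0.04 (adjusted p = 0.72) under ribosomal scaling. Here the median was 0.09, or -0.06 and -0.28 under those scalings, and the mean -0.43, with a camera adjusted p of 0.997. With fry both lists were lower, at adjusted p = 0.00187 for the activated and adjusted p = 9.42e-06 for the repressed genes. A difference between both lists was not tested.

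Over the whole course, the slope of log2 expression per hour was -1.57 (SE 0.11) for NFKBIA, -1.33 (SE 0.08) for PLK2, -1.17 (SE 0.07) for JUN, -1.16 (SE 0.08) for MYC and -0.37 (SE 0.05, edgeR adjusted p = 9.863e-06) for FLI1. MALAT1 had a slope of 0.50 (SE 0.04) and ANKRD36 one of 0.47 (SE 0.05). A negative slope was called for 3260 genes and a positive one for 3232. Scaled by library totals the counts were 4072 and 1348, and scaled to ribosomal protein mRNAs they were 6111 and 63, with the 3260 negative calls included in both. That inclusion follows from the scalings, which move all genes down together at 2 and 4 h.

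A change of rate was called for few genes without the replicate block and for many more with it, so how widespread it was depends on the model. ELF1, an ETS transcription factor gene, kept 63.2 ± 0.794 of 72.8 ± 2.87 CPM at 1 h and 49.2 ± 3.41 CPM at 2 h, then fell to 15.2 ± 1.09 CPM at 4 h, so that its log2 change from 2 to 4 h minus that from 0 to 2 h was -1.13 (SE 0.13, edgeR adjusted p = 0.003996). BCOR, a transcriptional corepressor gene, and ARHGAP24, a GTPase-activating protein gene, showed the same order with differences of -1.14 and -1.15. In the other direction DUSP6 fell from 249 to 21.0 CPM in the first 2 h and stood at 12.9 ± 0.673 CPM at 4 h, a difference of 2.87 (SE 0.17, adjusted p = 8.91e-06). ZNF526, ZNF574 and SOCS3 had differences of 2.70, 2.63 and 2.62. They were already low at 2 h, at 2.609 to 4.505, 2.802 to 4.408 and 2.428 to 4.541 CPM. At 4 h they stood at 2.545 to 3.66, 1.778 to 3.74 and 1.15 to 2.833 CPM. A fall that ends at a low level gives the same difference as a slower loss, and these were not told apart.

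In all, 49 genes had a slower fall or larger rise after 2 h and 29 a faster fall or smaller rise, against 944 and 697 with the replicate block, and 48 and 43 when scaled by library totals. In the model without the block these counts rested on single libraries. Without 0 h replicate 1, 2 or 3 they were 20 and 4, 14 and 4, and 43 and 12. Without 2 h replicate 1, 2 or 3 they were 17 and 4, 4 and 1, and 5 and 2. Without 4 h replicate 1 or 2 they were 28 and 13, and 18 and 3, and without 1 h replicate 2 they were 35 and 16. ELF1 and DUSP6 passed the threshold in all 12 fits that left out 1 library. ARHGAP24 lost its call in 8 of the 12 fits, namely without each library at 0 h, each at 2 h and 4 h replicates 2 and 3 (adjusted p up to 0.108). BCOR lost it in 6, without 0 h replicates 1 and 2, each library at 2 h and 4 h replicate 2 (adjusted p up to 0.108). SOCS3 lost it in 7, without 0 h replicates 1 and 2, each library at 2 h and 4 h replicates 1 and 3 (adjusted p up to 0.108), ZNF574 in 3, without 0 h replicate 2 and 2 h replicates 2 and 3 (adjusted p up to 0.106), and ZNF526 in 2, without 2 h replicates 2 and 3 (adjusted p up to 0.071). With the replicate block these had adjusted p-values of 0.0007871, 5.049e-05, 6.807e-05, 1.718e-05 and 7.98e-07, in the same order.

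Genes that fell early tended also to fall late. Across the 12775 tested genes the log2 change from 0 to 1 h and that from 2 to 4 h, which share no library, correlated at Pearson's r of 0.433 and a Spearman correlation of 0.501. This describes genes within these libraries, which are not independent replicates, and no p-value was computed.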

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

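Scaling by library totals and to ribosomal protein mRNAs was fixed in advance as an alternative for the named genes, whereas its use on the first and second hour of the immediate early list and the tests by background reads, replicate numbers and splits were chosen after the results were seen.

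In 7 named genes the change over the first 2 h differed from that over the second 2 h by the tested difference itself, on the log2 scale. It was -1.15 for ARHGAP24, -1.14 for BCOR and -1.13 for ELF1, whose loss was faster after 2 h. It was 2.87 for DUSP6, 2.70 for ZNF526, 2.63 for ZNF574 and 2.62 for SOCS3, whose fall was larger before 2 h. Of 100 splits of the 9 libraries at 0, 2 and 4 h, 5 gave at least the real 78 calls, and the highest other split gave 4716. The splits with 4716 and 4649 calls put all 3 libraries of 4 h in the place of 2 h, and 1 with 3558 put all 3 of 0 h there, so these large counts point to a structure of the samples, which is the time course itself, and are no measure of chance. The remaining split with 142 calls had its times mixed, so chance is left open for this count. All of these splits exchanged libraries across replicate numbers, in the model without the replicate block. Splits within replicate numbers were not run for the change of rate.

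For the comparisons with 0 h, 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 170 calls at 1 h, 1929 at 2 h and 6123 at 4 h, the highest other gave 0 in each, and the real split was the 1 of 10 with as many. Of the 10 splits 4 part all 3 replicate pairs, the real one among them, and the other 3 of these gave 0 calls as well. For the slope, 1 of 100 splits, the real one, gave as many as 6492 calls, and the highest other gave 1994. These splits exchanged libraries across replicate numbers. With times exchanged only within replicate numbers, 1 of 100 splits, the real one, gave as many. The highest other there, whose times correlated with the real ones at 0.848, gave 4769. Both shares were under 0.05, which argues against chance, although 100 splits cannot give a smaller share than this.

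The immediate early list fell by 0.58 ± 0.0530 per hour in the first hour and by 0.93 ± 0.170 per hour in the second on the log2 scale (SD, n = 3). The difference of 0.36 ± 0.121 was 0.42 under library totals and 0.50 under ribosomal scaling. Against TMM, these scalings moved the median of all genes by 0.003 and 0.005 at 1 h and by -0.056 and -0.138 at 2 h. They could therefore only enlarge the difference and do not decide whether the scaling of the libraries accounts for it. The second hour had the larger fall in 3 of 3 replicate numbers, which argues against a single replicate. A delay before actinomycin D stops transcription may account for it and stays open, because no library sampled the first minutes. No test of the list means across time was planned, and the order was found and tested on the same data.

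The 8 largest rises at 4 h under the naming rule were weighed against scaling to a shrinking pool, since any long-lived mRNA appears higher. Under scaling to ribosomal protein mRNAs 7 of the 8 kept their call, so these rose relative to those mRNAs. IGFN1 missed the threshold (edgeR adjusted p = 0.0508) with a log2 change of 1.304 left, which does not set it apart from the others in size. That scaling moved the median of all genes by -0.372 at 4 h, less than these rises, which were picked for their size. Without a spike-in, an RNA lost more slowly than ribosomal protein mRNAs would also appear higher. The kept calls therefore do not decide whether the shrinking pool accounts for the rises. Genomic DNA or other background reads would raise genes that are hardly expressed, but the summed CPM of 3926 genes under 0.1 CPM was 131 ± 3.40 at 0 h and 121 ± 3.57 at 4 h, a ratio of 0.924 (0.892 to 0.979 within replicate numbers). These CPM are of raw library totals. TMM factors were 1.0339 to 1.0394 at 0 h and 0.9223 to 0.949 at 4 h, so the ratio would be higher after TMM scaling, where it was not computed. Reads shared within the ANKRD36 family stay open, as does continued synthesis or processing of nuclear RNA in actinomycin D, which this design did not test.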

How the results depend on the processing

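The fits without all 4 libraries of one replicate number were chosen after seeing the data; the other alternatives were fixed beforehand. Counts are given as higher and lower, or as slower and faster loss after 2 h for the change of rate. The replicate block gave 322 and 802 at 1 h, 2037 and 2496 at 2 h, 4444 and 3934 at 4 h, 4215 and 3706 for the slope, and 944 and 697 for the change of rate; every gene called without it kept its call in these comparisons, and it ended no camera list call at the preset correlation. Testing against 1.5-fold left 0 and 8, 1 and 468, 56 and 1509, 30 and 1560, and 8 and 0, since that test asks for a larger change. Ribosomal scaling gave 25 higher genes at 2 h, 154 and 5854 at 4 h, 63 and 6111 for the slope and 30 with slower loss; library totals gave 143 higher at 2 h, 1346 at 4 h and 1348 with a positive slope. Both moved the median of all genes down at 2 and 4 h, by -0.138 and -0.372 under ribosomal scaling and -0.056 and -0.15 under library totals. DESeq2's Wald test gave 40 higher at 1 h and 77 and 68 for the change of rate, limma-voom gave 18 with faster loss, and no filter gave 264 higher at 2 h. With the compared time points alone the counts were 5 and 72 at 1 h, 216 higher at 2 h, and 21 and 9 for the change of rate; the cause was not tested. The correlation of early and late change was 0.568 at 5 CPM or more; the cause was not tested. Leaving out libraries or one replicate number gave 0 to 25 and 1 to 173 at 1 h, 11 to 433 and 627 to 1599 at 2 h, 1440 to 2955 and 2279 to 3309 at 4 h, 2045 to 3221 and 2592 to 3373 for the slope, and 2 to 43 and 0 to 23 for the change of rate. The lowest values came from the fits without replicate 1 or 2. Without replicate 3, with as few samples, lower counts at 1, 2 and 4 h were 173, 1599 and 3309, above those with all libraries; the cause was not tested. The 0 higher genes at 1 h compare with 22 in edgeR with all libraries, 40 in DESeq2 and 355 at an unadjusted p under 0.05. Under ribosomal scaling the log2 change at 4 h turned to -0.002 for EIF5A, -0.003 for PSMA7, -0.046 for PSMA3, -0.102 for HIST1H1C, -0.138 for HSPA9, -0.048 for EWSR1 and -0.041 for ACTB, all short of the threshold, and 30 other calls on named genes ended. HIST1H1C had no call before. HIST2H2BE, not called, ranged from -0.807 to 0.009, the latter without replicate 2. The ribosomal protein list at 1 h, not called, ranged from 0.038 to -0.031 relative to all genes, the latter without 1 h replicate 2 (adjusted p = 0.0422); the cause was not tested. Of 75 list tests, 19 calls ended with an estimated correlation, and with fry 1 call ended and 14 were gained. Of 1425 list values under alternatives 80 changed direction with no call in either fit, and these were not read as reversals, a rule set after a stricter version had been seen. At 9381855 to 10929000 counts per library, the model without the replicate block recovered 2-fold differences of rate in 31.3% of simulated genes. The counts of rate changes also rest on the model, as the replicate block gave more at the same depth.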

Other observations

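The gene lists in this part were fixed in advance, and all other tests, on matched lists, transcript properties and noncoding genes, were chosen after the main results were seen.

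Stress and lipid genes had members in both directions at 4 h under TMM, and next to none higher under ribosomal scaling, which left 154 of all 12775 tested genes called higher. Of 23 genes of the unfolded protein and integrated stress response 8 rose and 6 fell (8 and 6 adjusted over the list alone, 14 and 7 with the replicate block, 7 and 7 under library totals, 0 and 9 under ribosomal scaling), with CHAC1 down 15.4-fold, DDIT3 7.83-fold and XBP1 4.27-fold and the chaperone gene PDIA3 up 1.36-fold, a rise that was 0.07 on the log2 scale under ribosomal scaling. CHAC1 was left at 0.418 to 0.453 CPM at 4 h, which is few reads. Of 21 cholesterol genes 7 rose and 3 fell (7 and 3 adjusted over the list alone, 11 and 4 with the block, 3 and 3 under library totals, 1 and 9 under ribosomal scaling), with INSIG1, which restrains sterol synthesis, down 2.42-fold and SQLE, which encodes squalene epoxidase, down 1.47-fold. Of 14 heat shock proteins 6 rose and 2 fell (6 and 2 adjusted over the list alone, 1 and 2 under library totals, 0 and 6 under ribosomal scaling), the latter being DNAJB1 (3.10-fold) and BAG3 (1.54-fold). Of 23 apoptosis regulators 9 fell and 3 rose (9 and 4 adjusted over the list alone, 10 and 6 with the block, 11 and 0 under library totals, 15 and 0 under ribosomal scaling), with BMF down 5.11-fold and MCL1, a short-lived survival factor, down 3.57-fold. Of 19 NF-kappa-B linked genes 6 fell and 1 rose (6 and 1 adjusted over the list alone, 8 and 2 with the block, 6 and 0 under library totals, 10 and 0 under ribosomal scaling), with IRF1 down 7.61-fold and TNFAIP3 4.05-fold. Of 20 snoRNA host genes 8 fell and 4 rose (8 and 4 adjusted over the list alone, 9 and 0 under library totals, 13 and 0 under ribosomal scaling), with SNHG12 down 4.29-fold and SNHG7 2.63-fold.

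Of 35 splicing factors 10 rose and 10 fell (10 and 10 adjusted over the list alone, 16 and 15 with the block, 2 and 13 under library totals, 0 and 22 under ribosomal scaling), with SRSF5 down 1.66-fold. Of 31 G2/M genes 4 fell (2 adjusted over the list alone, 14 lower and 4 higher with the block, 11 lower under ribosomal scaling), AURKA by 1.70-fold, CKS2 by 1.44-fold, and CENPF and TTK by 1.60- and 1.75-fold, of which the CENPF call ended without 0 h replicates 1 or 3 or 4 h replicates 1 or 2 (adjusted p up to 0.137) and the TTK call without 0 h replicate 3 or 4 h replicates 1 or 2 (adjusted p up to 0.143). These CENPF and TTK fits used the model without the replicate block, and with the block and all libraries both calls held. CENPF went from 147, 113 and 183 to 90.9, 73.1 and 114 CPM in replicates 1, 2 and 3. TTK went from 27.9, 22.1 and 41.4 to 16.2, 13.1 and 23.0 CPM. Of 27 G1/S genes 2 fell (2 adjusted over the list alone, 8 lower and 15 higher with the block, 8 lower under ribosomal scaling), CDT1 by 2.17-fold and CDC25A by 2.02-fold. Of 73 replication-dependent histone genes in the table only 7 passed the filter in these libraries of polyadenylated RNA. Of these 7, 1, HIST1H2BK, rose 1.33-fold (1 adjusted over the list alone, 2 with the block, 0 under ribosomal scaling). The rest of the list was not tested, so these genes do not stand for histone mRNA as a class. None of these 10 lists was called by camera at 4 h, with adjusted p of 0.521 for the unfolded protein response, 0.264 for cholesterol, 0.521 for heat shock, 0.33 for apoptosis, 0.166 for NF-kappa-B, 0.198 for snoRNA hosts, 0.997 for splicing, 0.521 for G2/M, 0.944 for G1/S and 0.54 for histones. With fry the apoptosis regulators (adjusted p = 5.83e-06), snoRNA hosts (adjusted p = 0.000635) and NF-kappa-B linked genes (adjusted p = 0.00203) were lower. The rest of these lists had fry adjusted p-values of 0.127 or more. Median, mean and camera direction differed in sign for histones (median -0.05, mean 0.12, higher), the unfolded protein response (0.15, -0.30, higher) and heat shock proteins (0.09, -0.05, higher), and the last 2 medians turned to -0.23 and -0.29 under ribosomal scaling.

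The fall of the ZNF genes was weighed against their low expression and against transcript composition. Against 10000 random lists matched on mean expression the ZNF median was lower by 1.16 on the log2 scale (-1.164), which left 94.1% of its gap to all genes, and no random list had a median below -0.18. Against lists matched on expression, GC content and transcript length, for 363 of the 365 genes, it was lower by 1.07 (-1.071), with 86.5% of the gap left. Both results argue against these properties as the cause. As a hypothesis, short mRNA lifetime may be a property of this gene class. This was not tested, and the density of exon junctions, taken up next, was not among the matched properties.

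A hypothesis on transcript structure was that genes with few exon junctions lose their mRNA faster. Across 11671 protein-coding genes, which are not independent replicates, the slope correlated with junctions per kb of coding sequence at a Spearman coefficient of 0.438 (bootstrap 95% interval 0.421 to 0.454), and at 0.407 without the ZNF genes. The 2333 genes with the lowest junction density had a median log2 change of -0.69 at 4 h and the 2331 with the highest one of 0.23. Adjusted for expression, GC content and length the coefficient was 0.418, so junction density is a candidate explanation for part of the spread in loss rates, although what travels with it was not separated. AUUUA pentamers per kb of 3′ UTR, counted in 11397 genes, correlated with the slope at -0.18, but at -0.03 after that adjustment, so their relation could rest on composition and length.

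The rises of MALAT1 and KCNQ1OT1 raised the question whether noncoding RNA as a class was lost more slowly. The gene types counted as noncoding included pseudogenes beside long noncoding RNAs. Of 455 such genes 68 rose and 68 fell at 4 h. Their median log2 change of 0.01 lay at percentile 88.25 of 10000 expression-matched lists of coding genes, which decides neither way. Pseudogenes, whose reads can belong to near-identical mRNAs, were not set apart, so long noncoding RNA alone was not tested.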
